A study of Zea mays with 4 samples.

How the data were processed

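Total RNA from 2 inbred lines of maize, Cm489 and F98902, was labelled with biotin and hybridised to 4 Affymetrix maize genome arrays, with 2 samples per line. Per the labels, plants were grown in soil, the material was aerial and the stage was flower development. Each sample title carries a code of its own after the line name, which the labels do not explain. The labels do not state which organ was taken or whether the samples of a line came from separate plants. The p-values therefore cannot be taken to cover the spread between plants. Those of genes rest on the spread between these samples and on variances shared across probe sets, and those of lists on a comparison with other genes. The labels give 100 ug of RNA for Cm489 replicate 2, 102 ug for F98902 replicate 1 and 52 ug for F98902 replicate 2. The extraction note of Cm489 replicate 1 names the other Cm489 sample, so its amount was not used here.

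The deposited table holds 1 value per probe set and array, on a scale taken as log2. Per the submitters' processing notes the values were made with GCRMA, which corrects background, normalises between arrays and summarises the probes of a probe set. Its version and settings are not given in the sources used here. The base of the logarithm was taken as 2 from the range of the values, which ran from 1.18 to 15.28. Array medians were 7.04 and 7.11 for Cm489 and 6.99 and 7.05 for F98902. GCRMA pulls probe sets without specific signal to a low floor near 2 with little spread, so a probe set at the floor on both arrays of a line has a very small SD there. No detection calls were used, so a value at the floor gives no level. A difference from a line under log2 4 on both arrays is therefore given as a lower bound, taken against 4. The number of arrays limits the precision.

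Of 17734 probe sets, 113 controls were kept out of the tests, leaving 17621. A probe set was tested when its log2 value was at least 4 on at least 2 of the 4 arrays, which 11242 passed. Each was fitted with limma 3.58.1 (lmFit and eBayes, constant prior) in R 4.3.3, F98902 minus Cm489, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. SE is the moderated standard error of the difference. Samples with the same replicate number were not treated as pairs. An exact test of 2 against 2 arrays cannot give a two-sided p below 0.333.

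Gene names came from GEO's annotation of the platform, updated through Entrez gene numbers to the RefSeq annotation of the B73 assembly Zm-B73-REFERENCE-NAM-5.0. In it 1452 probe sets had 1 gene, 1 had several and 16168 were unnamed here. Of the 1452, 1377 matched a RefSeq gene. Among tested probe sets 976 had 1 gene, giving 811 genes. The deposited table names no genome build, so no coordinates are given.

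Before the data were examined, 20 gene lists were fixed by symbol, of which the first 8 concern the cell wall. A gene belonged to a list when its symbol or a synonym equalled a listed symbol. The hemicellulose, shikimate and cytosolic ribosomal protein lists found no named member, 9 lists had under 3 tested genes and were read gene by gene, and 8 were tested with limma's camera (preset correlation 0.01, 1 probe set per gene, the one with the highest mean). In 6 cases the matching gene shares only a symbol with the gene a list was meant for, such as dmt101, a DNA methyltransferase gene also called met1. These were kept, as the rule was written, and lists without them were run as an alternative. A further 21 families of related symbols were set after gene names and array correlations had been seen and before the values of genes were looked at.

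Genes to be named were chosen by a rule fixed beforehand: the 10 largest rises and 10 largest falls among named genes past the threshold with the arrays of the lines apart, up to 4 members with the smallest adjusted p from each wall list and up to 2 from each other list, and the brown midrib genes and bk2 where measured. Members of the 21 families named outside this rule were chosen after their values were seen.

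The fit was tested on simulated arrays for the same comparison, with the real means of the 11242 tested probe sets, variances drawn from the fitted prior and 200 changed probe sets in each of 10 runs. It recovered 61.2% of differences of 8 on the log2 scale, 0.597% of differences of 4 and 0% of differences of 2, and 4.67% of its calls were false. The simulation had independent noise and no structure shared between arrays. Its variances followed the prior that the fit assumes, and it had no floor with little spread. Its share of false calls therefore does not carry over to probe sets at the floor.

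Alternatives were no dim filter, a filter at log2 6, an intensity-dependent robust prior, each array shifted to 1 median, quantile normalization, the replicate number as a block, leaving out each array, 1 common variance with Bonferroni adjustment, no variance moderation, an added log2 difference of 1, an adjusted p under 0.01, all probe sets of a list, camera with an estimated correlation, and limma's fry. After the results were seen, values under log2 4 raised to 4 and all probe sets of a list with an estimated correlation were added. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.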

Results

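Transcript levels were measured on 4 arrays, 2 for each of the maize inbred lines Cm489 and F98902, in a series concerned with the diversity of the maize cell wall. The comparison asked which genes, and among them which cell wall genes, differed between the lines. All values are log2 signals, with mean ± SD over n = 2 arrays per line.

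The clearest differences between the lines were probe sets bright in one line and at the floor of the scale in the other. Absent expression and sequence differences between a line and the probes cannot be told apart here. The lower bounds below therefore concern probe signal and need not hold for transcript level. The first adjusted p beside each bound comes from the main fit to the deposited values and does not test the bound. HRGP (LOC542371), which encodes a hydroxyproline-rich glycoprotein of the cell wall, was at the floor in Cm489 (2.27 ± 0.02) and at 13.15 ± 0.52 in F98902, at least 9.15 higher (limma adjusted p = 0.0186). The ribosomal protein gene rpl30 (LOC541668) was at the floor (2.16 ± 0.02) and at 11.18 ± 0.17, at least 7.18 higher (adjusted p = 0.0186, and 0.0508 with an intensity-dependent robust prior). The gene mfs2 (LOC541978) was at the floor (2.43 ± 0.47) and at 7.59 ± 0.75, at least 3.59 higher (adjusted p = 0.0496). The mfs2 call was lost with no dim filter (adjusted p = 0.192), the robust prior (0.103), each array shifted to 1 median (0.0501) and values under log2 4 raised to 4 (0.104). No named gene passed the test with a lower level in F98902.

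In all, 200 of 11242 tested probe sets passed, 105 higher and 95 lower in F98902, and 196 of these 200 were unnamed here. The smallest difference among those that passed was 3.62 for higher and -3.70 for lower probe sets. In the simulated arrays 0% of differences of 2 and 0.597% of differences of 4 were recovered. A gene that did not pass is therefore not shown to be equal in the lines. Of the 105 higher, 92 lay below log2 4 on both Cm489 arrays, and of the 95 lower, 73 lay below log2 4 on both F98902 arrays. The count was 8 with an intensity-dependent robust prior, 9 without variance moderation, 0 at an adjusted p under 0.01 (limma, with 1183 at an unadjusted p under 0.05), 79 with no dim filter and 115 with values under log2 4 raised to 4, the last chosen after the results were seen. It was 0 when any 1 array was left out (without Cm489 replicate 1, Cm489 replicate 2, F98902 replicate 1 or F98902 replicate 2).

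**Figure D1:**
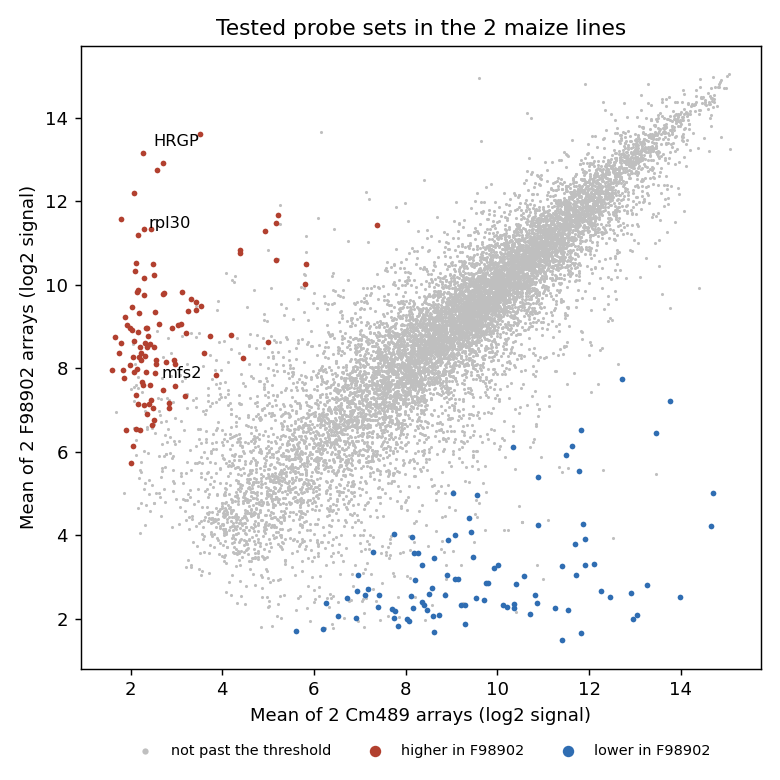
Mean log2 signal of each tested probe set in Cm489 (x axis, 2 arrays) and F98902 (y axis, 2 arrays), with the 105 probe sets higher and 95 lower in F98902 in colour. Most coloured points lie near the floor of one axis, among them HRGP, rpl30 and mfs2.

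Few lignin genes of the fixed lists were tested. The monolignol list had 2 tested genes, PAL1 and BM1, and the laccase and peroxidase list 2, LAC1 and per-1. None of these passed over all probe sets, which does not extend to the rest of the pathway. No brown midrib gene other than BM1 was among the tested named genes. In the phenylpropanoid and lignin family, set after gene names were seen, 0 of 9 tested genes passed. BM1 (LOC542663), the cinnamyl alcohol dehydrogenase gene of the brown midrib1 locus, was at 12.59 ± 1.87 in Cm489 and 12.59 ± 1.67 in F98902, and PAL1 (LOC542258), for phenylalanine ammonia-lyase, at 14.30 ± 0.38 and 14.33 ± 0.28. LAC1 (LOC606456), a laccase gene, was at 10.21 ± 0.92 and 9.58 ± 0.19. The gene per-1 (LOC100037830), which matched the peroxidase list by symbol alone, is not taken as a lignin gene. It was at 7.85 ± 1.32 in Cm489 and at the floor in F98902 (2.04 ± 0.03, limma adjusted p = 0.0675). It passed when adjusted over the list alone, which held only 2 tested genes. The MYB genes myb31 (LOC100037768) and myb42 (LOC100101513), known repressors of lignin genes, differed by -2.27 (SE 0.68, adjusted p = 0.373) and -1.38 (SE 0.66, adjusted p = 0.653). Neither passed, and myb42 ran from -0.64 (without F98902 replicate 1) to -2.11 (without F98902 replicate 2).

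Among 10 tested cellulose synthesis genes 7 were lower and 3 higher in F98902, and 0 passed, also when adjusted over the list alone. The median difference was -0.63 and the list did not pass (camera adjusted p = 0.514, and 0.884 with an estimated correlation). The cellulose synthase gene cesa2 (LOC542564) differed by -1.67 (SE 0.52, adjusted p = 0.396), cesa8 (LOC541806) by -1.21 (SE 0.68), cesa3 (LOC542489) by -1.19 (SE 0.93), and bk2 (LOC778435), the brittle stalk2 gene of a COBRA-like wall protein, by -1.15 (SE 1.07). With 1 array left out, cesa8 ran from -1.79 (without F98902 replicate 1) to -0.64 (without F98902 replicate 2), cesa3 from -2.14 to -0.24 (the same arrays) and bk2 from -2.33 (without Cm489 replicate 1) to 0.0244 (without Cm489 replicate 2). Without Cm489 replicate 1 the list had an adjusted p of 0.0140 and without F98902 replicate 1 of 0.0349, both lower in F98902. Its direction turned without Cm489 replicate 2 (adjusted p = 0.952) and without F98902 replicate 2 (adjusted p = 0.929).

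Several wall genes differed more between the arrays of a line than between the lines. The secondary wall cellulose synthases cesa10, cesa11 and CesA12, named after their values were seen, were 3.26 to 3.90 higher in replicate 2 than in replicate 1 of Cm489, and replicate 2 minus replicate 1 of F98902 ran from -2.70 to -2.15. BM1 shifted by 2.64 and -2.37 and bk2 by 2.35 and -1.57. The same arrays differed in a measure of RNA integrity, the 5' minus 3' signal of control transcripts, where replicate 2 minus replicate 1 was 0.59 in Cm489 and -0.82 in F98902 for cyclophilin, and 0.83 and -1.63 for GAPDH. For ubiquitin it was 0.05 and 0.24, and for EF1-alpha -1.02 and -1.10. The 5' minus 3' signal of EF1-alpha also separated the lines, at -3.42 and -4.44 in Cm489 and -1.88 and -2.97 in F98902. For cyclophilin, GAPDH and ubiquitin the arrays of the lines overlapped. Whether RNA integrity contributed to the differences between the lines was not tested.

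**Figure D2:**
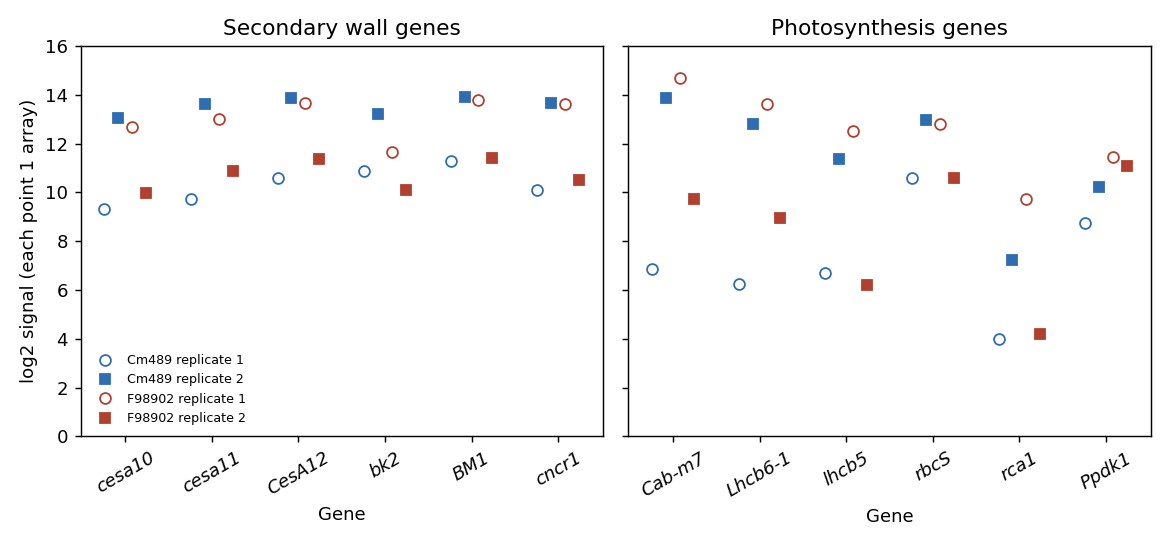
Log2 signal of 6 secondary wall genes (left) and 6 photosynthesis genes (right), each point 1 array. In BM1, the arrays of a line lie 2.64 (Cm489) and 2.37 (F98902) apart around equal means of 12.59.

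GRP, expa1 and xet1, the other tested genes of the structural and wall-remodelling lists, did not pass, which does not show equal levels. GRP (LOC542562), for a glycine-rich protein, was at 13.89 ± 0.17 in Cm489 and 13.87 ± 0.09 in F98902, the expansin gene expa1 (LOC541904) at 11.30 ± 1.32 and 9.87 ± 0.52, and the xyloglucan endotransglycosylase gene xet1 (LOC542312) at 13.08 ± 0.69 and 13.81 ± 0.35. The difference in expa1 was -2.37 without Cm489 replicate 1 and -0.50 without Cm489 replicate 2, and that in xet1 1.22 and 0.24. The only member of the methyl donor list, dmt101 (LOC542082), a DNA methyltransferase gene matched through its second name met1, was at 9.74 ± 0.58 and 9.26 ± 1.13.

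None of the 8 tested lists passed, with adjusted p from 0.514 to 0.871, and HRGP was the 1 list member past the threshold over all probe sets. In the photosynthesis list 3 of 5 genes were higher in F98902, with Ppdk1 (LOC542759), for the dikinase of C4 photosynthesis, at 9.50 ± 1.04 and 11.27 ± 0.26. PDK1 (LOC541677), matched by symbol alone, was at 7.56 ± 0.78 and 8.52 ± 0.40. The difference without Cm489 replicate 1 and without Cm489 replicate 2 was 1.03 and 2.505 for Ppdk1 and 0.40 and 1.504 for PDK1. The list passed with all probe sets counted (adjusted p = 0.0128), and not when these were tested with an estimated correlation (adjusted p = 0.899 with an estimated correlation). Over its alternatives adjusted p ran from 0.0128 to 0.899. Its median replicate 2 minus replicate 1 was 1.47 in Cm489 and -0.57 in F98902. Among 5 meristem and cell division genes 2 were higher, the median was -0.54 while camera's direction was upward, and his1 (LOC542385), a histone gene, was at 2.75 ± 0.03 and 5.62 ± 0.47 (adjusted p = 0.109). 1 gene of this list passed when adjusted over the list alone. The homeobox gene lg3 (LOC542487) differed by 1.08 (SE 0.59), by 1.70 without Cm489 replicate 1 and by 0.45 without Cm489 replicate 2.

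In the vascular transport list 4 of 5 genes were lower in F98902, with the sucrose synthase gene sus2 (LOC542091) differing by -1.14 (SE 0.40, adjusted p = 0.461) and the sucrose transporter gene sut1 (LOC541615) by -0.92 (SE 0.45). In the pathogen list pr5 (LOC542720), a thaumatin-like gene, differed by 2.89 (SE 0.75, adjusted p = 0.296) and the chitinase gene chn1 (LOC542525) by -0.91 (SE 0.83), the list median being -0.91 against an upward camera direction. Of 4 benzoxazinoid genes 2 were higher, with glu1 (LOC542414), a beta-glucosidase gene, at -2.43 (SE 1.08) and bx1 (LOC542117), the first gene of the pathway, at 3.06 (SE 1.77). Of 4 stress genes 2 were higher, with hsp101 (LOC541780) at 1.45 (SE 1.51) and adh2 (LOC542364) at -0.85 (SE 0.52). Of 4 kernel genes 2 were higher, with SBEIIb (LOC542238), a starch branching enzyme gene, at -0.96 (SE 0.72) and the zein gene gz27 at -0.85 (SE 1.24). Without F98902 replicate 1 and without F98902 replicate 2, bx1 was at 1.11 and 5.002, hsp101 at -0.56 and 3.45 and chn1 at 0.10 and -1.93. Without Cm489 replicate 1 and without Cm489 replicate 2, glu1 was at -1.38 and -3.47, adh2 at -1.32 and -0.38, sut1 at -1.22 and -0.61, SBEIIb at -1.78 and -0.14 and gz27 at -2.30 and 0.59.

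Of the smaller lists, the anthocyanin gene a2 (LOC606406) was at 9.28 ± 0.18 in Cm489 and 9.28 ± 2.57 in F98902. TUA1 (LOC100037751), an alpha-tubulin gene of the pollen list, was at 10.88 ± 0.46 and 11.46 ± 0.45. The wax gene gl8 (LOC542359) was at 10.17 ± 0.48 and 9.34 ± 0.62, and fdh (LOC542459), matched by symbol alone, at 10.52 ± 0.06 and 10.94 ± 0.60. None of these 4 genes passed. Without F98902 replicate 1 and without F98902 replicate 2 the difference was 1.81 and -1.82 in a2, -0.39 and -1.26 in gl8 and -0.00619 and 0.84 in fdh, and without Cm489 replicate 1 and without Cm489 replicate 2 it was 0.26 and 0.91 in TUA1.

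Among the 21 families of related symbols, set after gene names and array correlations were seen, aquaporins and expansins were lower and photosynthesis genes higher in F98902 (camera adjusted p = 0.0419 for each of the 3). All 3 calls were lost with an estimated correlation (adjusted p = 0.826 with an estimated correlation) and with no dim filter (0.202 for expansins, 0.0763 for aquaporins and 0.143 for photosynthesis genes). In F98902 18 of 21 aquaporin genes were lower (median -0.92), 7 of 7 expansin genes were lower (median -2.29) and 15 of 18 photosynthesis genes were higher (median 1.29), and no single member passed over all probe sets, while 1 expansin gene passed when adjusted over the list alone. Replicate 2 minus replicate 1 had a median of 1.57 in Cm489 and -1.21 in F98902 for aquaporins, 1.87 and 1.17 for expansins, and 2.06 and -2.99 for photosynthesis genes. The counts of lower and higher genes rest on means of 2 arrays. F98902 replicate 2 lay at or above both Cm489 arrays for 3 of the 18 photosynthesis genes, 1 aquaporin gene and 1 expansin gene. F98902 replicate 1 lay below both for 2 photosynthesis genes, 7 of the 21 aquaporin genes and 5 of the 7 expansin genes. The 5' minus 3' shifts of the 4 control transcripts had medians of 0.32 and -0.96, with ubiquitin (0.05 and 0.24) and EF1-alpha (-1.02 and -1.10) not running opposite ways in the lines. The 5' minus 3' signal of EF1-alpha and the signal of the 18S rRNA control were lower on both Cm489 arrays than on both F98902 arrays. The 5' minus 3' signals of cyclophilin, GAPDH and ubiquitin overlapped between the lines. The photosynthesis call was lost without Cm489 replicate 1 (adjusted p = 0.701) and without F98902 replicate 1 (0.732), the aquaporin call without Cm489 replicate 2 (0.764) and without F98902 replicate 2 (0.374), and the expansin call without Cm489 replicate 2 (0.654) and without F98902 replicate 1 (0.254). The other 18 families had adjusted p from 0.0616 to 0.978.

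**Figure D3:**
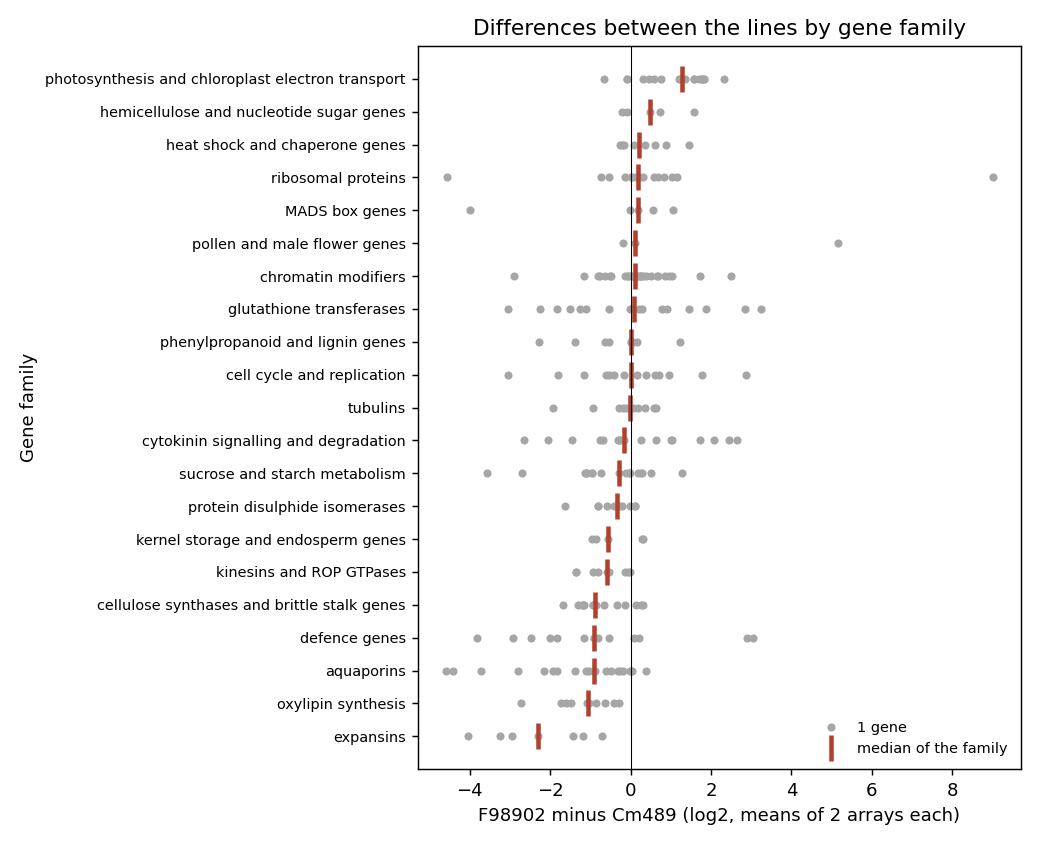
Difference F98902 minus Cm489 in log2 (x axis) for each gene of the 21 families (y axis), each grey point 1 gene and each bar the family's median. Medians run from -2.29 for expansins, the value of expA3 (SE 2.53), to 1.29 for photosynthesis genes.

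Over all probe sets the arrays of a line correlated at r = 0.952 for Cm489 and 0.938 for F98902. Between lines r ran from 0.899 (Cm489 replicate 1 with F98902 replicate 1) to 0.945 (Cm489 replicate 1 with F98902 replicate 2), which is above the value within F98902. These correlations are across probe sets, which are not independent replicates. The median SD between the arrays of a line was 0.22 in Cm489 and 0.26 in F98902.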

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

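The tests with crossed pairing, homonyms left out, values raised to log2 4, all probe sets with an estimated correlation, and of the families were chosen after data or names had been seen. The count of 200 probe sets (105 higher, 95 lower in F98902; 1183 at an unadjusted p under 0.05) stayed within 1.5 times under a filter at log2 6, both scalings, a common variance and an added log2 difference of 1. It was 79 (42 and 37) with no dim filter, 8 (4 and 4) with a robust prior, 9 (3 and 6) without variance moderation, 115 (53 and 62) with values under log2 4 raised to 4 and 0 (0 and 0) at an adjusted p under 0.01. Leaving out each array gave 0 to 0 with limma, where the lone array is assumed to vary like the other line. With the replicate number as a replicate block the count was 0. The labels do not say that the numbers pair samples, and within-line differences correlated at -0.558; the crossed pairing gave 284 probe sets, 142 higher and 142 lower. List members past the threshold numbered 1, against 0 with no dim filter, the robust prior, the block and each left-out array, and 2 with all probe sets. That member is HRGP by the list's probe set (adjusted p = 0.0865 with no dim filter); its other probe set kept the call there (0.0393). The cause was not tested.

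Of 119 values of the 8 lists 106 kept direction and side of the threshold, 10 turned and 3 passed. None of the lists passed in the main setting, so keeping side means only that a list still did not pass. The photosynthesis list passed with all probe sets (adjusted p = 0.0128), and not with these and an estimated correlation (adjusted p = 0.899 with an estimated correlation). Directions turned for heat shock with no dim filter (0.948), cell division with a filter at 6 (0.847) and benzoxazinoids with the block (0.884). Over left-out arrays adjusted p ran from 0.0140 to 0.952 for cellulose synthesis, 0.712 to 0.929 for benzoxazinoids, 0.488 to 0.975 for kernel genes, 0.139 to 0.952 for the pathogen list and 0.707 to 0.952 for heat shock, each with a turn. Leaving out homonyms changed no call. The cause was not tested.

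Of 394 values of 36 named probe sets 348 kept side and direction, 27 lost the call and 19, of 11 probe sets, turned. Only 4 of these probe sets passed in the main fit, so all 27 lost calls are theirs. For the others, keeping side means only that they still did not pass. With equal medians GRP turned to 0.0608 and a2 to 0.0704, and with quantile normalization BM1 to -0.00763 and a2 to 0.0526. Over left-out arrays differences ran from -0.25 to 0.29 (PAL1), -1.32 to 1.32 (BM1), -1.27 to 0.0225 (LAC1), -2.33 to 0.0244 (bk2), -0.14 to 0.11 (GRP), -1.28 to 0.32 (dmt101), -1.82 to 1.81 (a2), -2.30 to 0.59 (gz27), -1.93 to 0.10 (chn1), -0.56 to 3.45 (hsp101) and -0.00619 to 0.84 (fdh). Among probe sets past the dim filter mean r was 0.839 within and 0.747 between lines, and median SD 0.45 (Cm489) and 0.52 (F98902). Signal over background limits probe sets near the floor.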

Other observations

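All tests of explanations in this part were chosen, or were given their final form, after results had been seen, and the families were set after gene names and array correlations were seen. The mean of F98902 was lower for 10 of 10 oxylipin genes (median -1.06, camera adjusted p = 0.0616), but for 5 of them F98902 replicate 2 lay at or above both Cm489 arrays, and replicate 2 minus replicate 1 had a median of 1.83 in F98902. Among those lower on both F98902 arrays were opr7 (difference -2.72) and lox1, a lipoxygenase gene (-1.73), both named after their values were seen. All 9 kinesin and ROP GTPase genes had lower means too (median -0.58, camera adjusted p = 0.238), with replicate 2 minus replicate 1 at a median of 1.26 in Cm489 and -0.79 in F98902. F98902 replicate 2 lay at or above both Cm489 arrays for 0 of these genes, but F98902 replicate 1 lay below both for only 3. The ribosomal protein family had a median difference of 0.18, while RPS21, also named after its value was seen, differed by -4.57 (SE 0.93, adjusted p = 0.189). The 18S rRNA control was at 6.996 and 7.68 in Cm489 and at 9.69 and 8.28 in F98902.

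By replicate number, differences between the arrays of a line ran opposite ways in the 2 lines (correlation of replicate 2 minus replicate 1 across tested probe sets -0.558). Medians were 5.61 in Cm489 and -5.31 in F98902 for light-harvesting genes and 3.71 and -2.30 for the secondary wall cellulose synthases. Because the labels do not pair replicate numbers across the lines, the sign of this correlation is arbitrary. Numbering the arrays of 1 line the other way would turn it. The pattern is therefore that the same genes shifted together within both lines. Samples swapped between the lines are argued against, since the labelled lines split 112 probe sets into both arrays under 3 against both above 7, and the crossed grouping 5. RNA degradation stays open. The median 5' minus 3' shift of the 4 control transcripts was 0.319 in Cm489, far under that of the secondary wall cellulose synthases, with EF1-alpha running the other way (-1.02). In F98902 it was -0.956, the way of the pattern but smaller. Those cellulose synthases were named after their values were seen, which bears on the comparison of sizes. The whole cellulose synthase and brittle stalk family had median shifts of 1.04 in Cm489 and -1.12 in F98902. A different share of green leaf tissue is left open too, although the written bound for arguing against it was met. Ppdk1 and ME1 had a median shift of 1.13 in F98902, against the light-harvesting genes, and of 0.95 in Cm489, with them. A further condition, not in the written bound, asked that an opposing median exceed the SD of the genes. It was not met in F98902, where the 2 genes lay far apart (-0.37 and 2.63). The gene pep1, at 2.86, 6.01, 2.79 and 2.37 over the 4 arrays, failed the dim filter. A hypothesis is that the samples may hold tissue of different developmental age. In a comparison with 10000 random lists the cell cycle family lay at percentile 0.25 in Cm489, within the extreme 5%. In F98902 it lay at percentile 93, the predicted side but outside the extreme 5%. The bound first written asked the extreme 5% of both lines, so the first run argued against this hypothesis. Only a bound rewritten after that result leaves the hypothesis open.

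The second pattern is the 112 probe sets at the floor in one line and bright in the other, 66 bright in F98902 and 46 in Cm489. Spread between samples of a line is argued against as the whole source, since the other pairings of the arrays gave at most 5, although 98 probe sets split the same way between the single arrays of Cm489 and 102 between those of F98902. Sequence differences between a line and the probes could leave a transcript unseen, and other probe sets of the gene should then stay level. The test counts only probe sets designed on another sequence, which leaves out the other probe set of HRGP; among named genes it first found none, so after that run it was widened to probe sets sharing a cluster number in their ID, which need not be the same gene, with unchanged bounds: in 29 of 95 pairs (30.5%), which lies between the bounds, the partner differed the same way by at least 0.5 times as much, but the pairs cover 20 of the 112, hold 49 different partners with some pairs counted both ways, and 60 come from 1 cluster (outside it 11 of 35). Sequence differences and absence of expression in one line cannot be told apart here, since few of the 112 have another probe set, and the difference in lines itself was not tested as an explanation.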
